A study of Homo sapiens with 6 samples.

How the data were processed

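RNA was measured in 6 libraries of 2 human clear cell renal cell carcinoma lines. Per the labels' protocols, cells were transduced with retroviral short hairpin constructs from a commercial collection, with virus packaged in HEK293T, a human embryonic kidney line, and selected with puromycin, and total RNA was made into libraries with a TruSeq Stranded Total RNA kit. Each line carried a non-targeting control, ZNF395 hairpin 1 or ZNF395 hairpin 3, and each library's group came from its own labels. The guide sequences of the hairpins and of the control are not given in the sources used here. No label gives a sequencing batch or date, so no comparison could be repeated within batches.

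The file analysed holds whole-number read counts per gene symbol for the 6 libraries, deposited by the authors without normalization, for 32357 genes. Per the submitters' processing notes, STAR, DESeq2, hg19 and hs37d5 were used, with no versions or roles. The counting tool, the gene annotation and the strand setting are not given in the sources used here. No gene in the deposited table has a summed count under 2, so genes with fewer reads are absent from it. A counter that ignores strand adds up a gene and its antisense partner, and 1 that discards reads with several matches lowers genes with near-identical copies. Genes named in the text to which this applies, such as ACTG1, PCDHA10, RNU6-1 and the histone genes, are therefore uncertain, as are genes that overlap others in the annotation (ZNF395, HMGA2, PTGER4, KREMEN1, SESN3 and HSD17B10). The authors also deposited a mean signal per gene, which was recomputed from the counts with DESeq2's size factors (median absolute difference 2.4e-09), and, per the file headers, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value from DESeq2. The authors' deposited log2 fold change sets control over knockdown, which was read from its sign against the counts. The adjusted p-value of the authors is not given for 16311 genes. The design of the authors' model is not given in the sources used here. No number column of the file was left unlisted (0).

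Library totals ran from 77534125 to 99147218 counts. Genes encoded in mitochondrial DNA took 5.45, 5.41 and 5.13% of the counts in the control, hairpin 1 and hairpin 3 libraries of 786-O and 8.21, 7.02 and 7.37% in those of A-498. The 10 most abundant genes took 5.68 to 8.28%. At this depth a gene at 1 CPM has 77.5 to 99.1 counts before scaling. Intervals on ZNF395 are 95% counting intervals, a count of 0 allows up to 3 counts, and both cover counting error only.

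Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F tests after TMM scaling, in which 20144 genes passed edgeR's expression filter over knockdown status), with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. Standard errors were derived from the F statistic. Knockdown against control and A-498 against 786-O came from a model with line and knockdown status (3 residual degrees of freedom), knockdown within each line and the difference between lines from a model with 4 means (2 residual degrees of freedom), and each hairpin against the control and hairpin 3 against hairpin 1 from a model with line and construct (2 residual degrees of freedom). In the last model the lines serve as replicates. CPM values are TMM-scaled, and log-CPM used a prior count of 2. Correlations over genes used genes with a mean of at least 5 CPM.

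The replicate numbers in the labels are the hairpin numbers, so libraries of the same number received the same reagent in both lines. The difference between hairpin 3 and hairpin 1 correlated between the lines over genes (Pearson r 0.577, Spearman 0.556), and the knockdown models were also fitted with the hairpin as a block. The controls carry neither hairpin, so the hairpin lies within the knockdown group, and the blocked fold is the average of the hairpins. The block leaves 2 residual degrees of freedom with line and knockdown status, where the fit equals the model with line and construct, and 1 with 4 means. Blocked values stand beside the results whose calls they change.

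The lists, 30 in all, were written before the data were examined, together with the models, the alternatives and the rule for named genes. They hold HIF targets, glycolysis, nuclear OXPHOS, mtDNA-encoded genes, mitochondrial biogenesis and ribosome, TCA cycle and beta-oxidation, interferon-stimulated genes, NF-kB inflammatory genes, proliferation, p53 targets, cholesterol synthesis, fatty acid and lipid droplet genes, PPARG and adipogenesis, the ATF4 response, the UPR, EMT and matrix, TGF-beta, YAP/TEAD and NRF2 targets, immediate early genes, apoptosis, lysosome and autophagy, renal tubule identity, ccRCC-associated genes, ribosomal proteins, replication-dependent histones, and endothelial, immune, fibroblast and HEK293-associated markers. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation, and with fry. With an estimated correlation camera rests on the residual degrees of freedom of the model, 3 or 2 here. With so few, hardly any list can pass after adjustment, so a failure in that setting does not show an absent shift.

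Named genes are ZNF395; for knockdown against control, genes with the same sign in all 4 ratios, a symbol and a mean of at least 5 CPM, the 12 up and 12 down of largest fold among those called, or the 8 per direction of smallest p where fewer than 5 were called; up to 4 members per list of smallest knockdown p with a mean of at least 1 CPM; and for the line difference, the hairpin difference and the lines, 5 per direction by fold among called genes, or 3 by p where none was called. Genes of the X inactivation centre and Y-linked genes were not named, and some genes that the rule names are not reported here. Genes called with both hairpins or with the block, and those said so in the text, were picked after their values were seen. Coordinates and overlaps come from GENCODE release 29 on GRCh38, not from the authors' hg19.

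The tests named here were run on simulated counts with 200 genes of at least 5 CPM changed by known folds. Hairpin 3 against the control and knockdown within A-498 were not simulated. For knockdown against control (19750 genes) the test recovered 33% of 2-fold and 96% of 4-fold changes with 7 false calls among 136. There both hairpins had the same effect, whereas 1910 real genes differed between the hairpins, so real recovery may be lower. ZNF395 itself, at a log2 fold change of -2.29, had an adjusted p = 0.358 in that edgeR test. Within 786-O (19743 genes) it recovered 0% and 58%, with 7 false among 65, and for the difference between lines (19733 genes) 0% and 3%, with 0 false among 3. For hairpin 1 against the control (19788 genes) it recovered 88% and 100%, with 30 false among 218, for hairpin 3 against hairpin 1 (19801 genes) 85% and 100%, with 29 false among 214, and for the lines (19514 genes) 40% and 98%, with 20 false among 158. Except for the difference between lines, the false shares lie above the nominal 5%, though only slightly for knockdown against control. Genes close to the threshold are therefore less certain than their adjusted p states.

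Alternatives tried were DESeq2's size factors, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, robust dispersions, no line term, the hairpin block and leaving out each library. Motifs in 3' untranslated regions were counted as 7-mers over 10088 of 11027 genes with a mean of at least 5 CPM and an annotated region, with folds limited to 2 on the log2 scale and 7-mers in fewer than 50 genes set to no shift. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for summaries and plots.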

Results

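The transcriptomes of 2 human clear cell renal cell carcinoma lines, 786-O and A-498, were measured with and without knockdown of ZNF395, a zinc finger protein. Clear cell carcinoma is the commonest cancer of the kidney, and both lines lack a working VHL tumour suppressor. Each line had received 1 of 3 retroviral short hairpin RNA constructs: a non-targeting control, ZNF395 hairpin 1 or ZNF395 hairpin 3. This gave 6 libraries, 1 per line and construct, so that 4 knockdown libraries stood against 2 controls. The total count was 79709917 in the 786-O control, 80483251 with hairpin 1 and 78841052 with hairpin 3. In A-498 it was 99147218 in the control, 77534125 with hairpin 1 and 93634021 with hairpin 3. Since each line and construct had 1 library, no spread between repeat cultures was measured. The p-values therefore rest on the spread that each model leaves between these libraries. With both hairpins pooled, that spread includes the difference between the hairpins. With line and construct in the model, it is the difference between the lines in the response to a construct.

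ZNF395 itself was lower in all 4 knockdown libraries. In 786-O it stood at 96.3 CPM, the count scaled to the library total, in the control, 24.7 with hairpin 1 and 13.5 with hairpin 3. In A-498 it stood at 67.9 CPM in the control, 14.5 with hairpin 1 and 14.3 with hairpin 3. In 786-O 25.6% of the control level remained with hairpin 1 (95% counting interval 24.4 to 26.9%) and 14.0% with hairpin 3 (13.1 to 14.9%). In A-498 the values were 21.4% (20.1 to 22.8%) and 21% (19.8 to 22.3%). These intervals cover counting error only. Tested over both lines with edgeR, ZNF395 fell with hairpin 1 (log2 fold change -2.08, SE 0.209, adjusted p = 0.0269) and with hairpin 3 (-2.52, SE 0.213, adjusted p = 0.00973). The hairpins did not differ significantly from each other (difference -0.44, SE 0.205, adjusted p = 0.217). ZNF395 lies on chromosome 8 at 28345585 to 28402701 on the minus strand in GRCh38, where it overlaps FBXO16 on the same strand, so its counts are uncertain to that extent.

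The main question was which genes change when ZNF395 is knocked down, with both hairpins pooled against the control within each line. Besides ZNF395 (log2 fold change -2.29, SE 0.235), the smallest p-values belonged to DYNLRB1, a light chain of the dynein motor (1.38, SE 0.140), GFPT2, an entry enzyme of the hexosamine pathway (1.20, SE 0.154), and the Ras-family GTPase MRAS (-1.09, SE 0.140). Other genes at the top with higher levels in all 4 knockdown libraries were HSD17B10, a mitochondrial dehydrogenase (1.11), the chromatin protein HMGA2 (1.44), the prostaglandin E2 receptor PTGER4 (1.28), the MAP kinase phosphatase DUSP16 (0.99), DDA1 (0.73) and the AMPK-related kinase NUAK2 (1.02). Genes with lower levels in all 4 were SESN3 of the sestrin family (-1.45), HHIPL2 (-1.21), the receptor FGFR3 (-1.51), the cytoplasmic actin ACTG1 (-1.22), the matrix protein VWA1 (-1.05) and the lipid phosphatase PPAP2B (-1.30). None of these passed edgeR's test over 20144 genes, with adjusted p between 0.358 for ZNF395 and DYNLRB1 and 0.893. Of all genes, 0 rose and 0 fell in edgeR's quasi-likelihood test, with 1013 at an unadjusted p under 0.05. DESeq2 called 51 up and 41 down (1073 at an unadjusted p under 0.05), and limma-voom 0 up and 1 down (1124), the small nuclear RNA gene RNU6-1.

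With the hairpin as a block in the edgeR model, 26 genes changed between knockdown and control, 9 up and 17 down. The controls carry neither hairpin, so this is no separate knockdown test but the average of the fold changes of the 2 hairpins in the model with line and construct. ZNF395 fell by 2.30 on the log2 scale (adjusted p = 0.0176), and DYNLRB1 (1.38, adjusted p = 0.0176), HMGA2 (1.42, adjusted p = 0.0176), GFPT2 (1.20), PTGER4 (1.27) and HSD17B10 (1.11, each adjusted p = 0.0478) rose. KREMEN1, a Dickkopf receptor of the Wnt pathway (-1.77, adjusted p = 0.0176), the sulfatide-forming GAL3ST1 (-0.90), MRAS (-1.09) and SESN3 (-1.43, each adjusted p = 0.0478) fell. The same block called the receptor genes IL7R (1.54) up and FGFR4 (-1.14) down, the cyclin gene CCNE1 (-1.17), the NAD-synthesis gene QPRT (-1.67), the tight junction gene CLDN2 (-1.5) and ANXA5 (-1.28) down. Of the 26 genes, 23 had the same sign in all 4 ratios to the control, but 15 also differed between the hairpins. ANXA5, for example, stood at 565 CPM in the 786-O control, 110 with hairpin 1 and 604 with hairpin 3, so that its average fall came from hairpin 1.

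A stricter count took genes called against the control with each hairpin on its own, and 8 genes met it, 5 up and 3 down. DYNLRB1 rose by 1.38 with hairpin 1 (adjusted p = 0.0215) and 1.39 with hairpin 3 (adjusted p = 0.00973), from 49.8 to 135 and 134 CPM in 786-O and from 24.2 to 60.2 and 62.2 CPM in A-498. HMGA2 rose by 1.21 (adjusted p = 0.0260) and 1.64 (adjusted p = 0.00754), PTGER4 by 1.44 (0.0412) and 1.1 (0.0173), GFPT2 by 1.18 (0.0473) and 1.23 (0.0130), and NUAK2 by 1.17 (0.0495) and 0.85 (0.0225). KREMEN1 fell by 2.36 (adjusted p = 0.0151) and 1.18 (0.0143), a difference between hairpins that was itself significant (1.18, SE 0.150, adjusted p = 0.0108), and GAL3ST1 fell by 1.11 (0.0308) and 0.70 (0.0232). ZNF395 was the eighth gene, and 0 genes were called in opposite directions. Independent lists of the same lengths would share 0.2 genes up and 0.91 down, and 20 simulations with no effect but the same shared controls gave at most 3. In those simulations neither hairpin changed any gene. They therefore do not bound the overlap that shared controls could give between lists as long as the real ones, of 30 and 1351 genes. Each line has 1 control, which both hairpins share and which cannot be split, so part of the excess may come from the shared controls. Without the 786-O hairpin 1 library 0 genes were called with both hairpins, without the A-498 control 2, without the A-498 hairpin 1 library 5, without the 786-O control 17, and without the hairpin 3 library of 786-O or A-498 145 and 165. Each fit without a library has 1 residual degree of freedom and 1 library of the construct concerned, so these numbers of called genes are unstable. HMGA2 and PTGER4 overlap genes on the opposite strand and KREMEN1 an antisense gene, and the use of strand in counting is not stated, so their counts are uncertain to that extent.

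**Figure D1:**
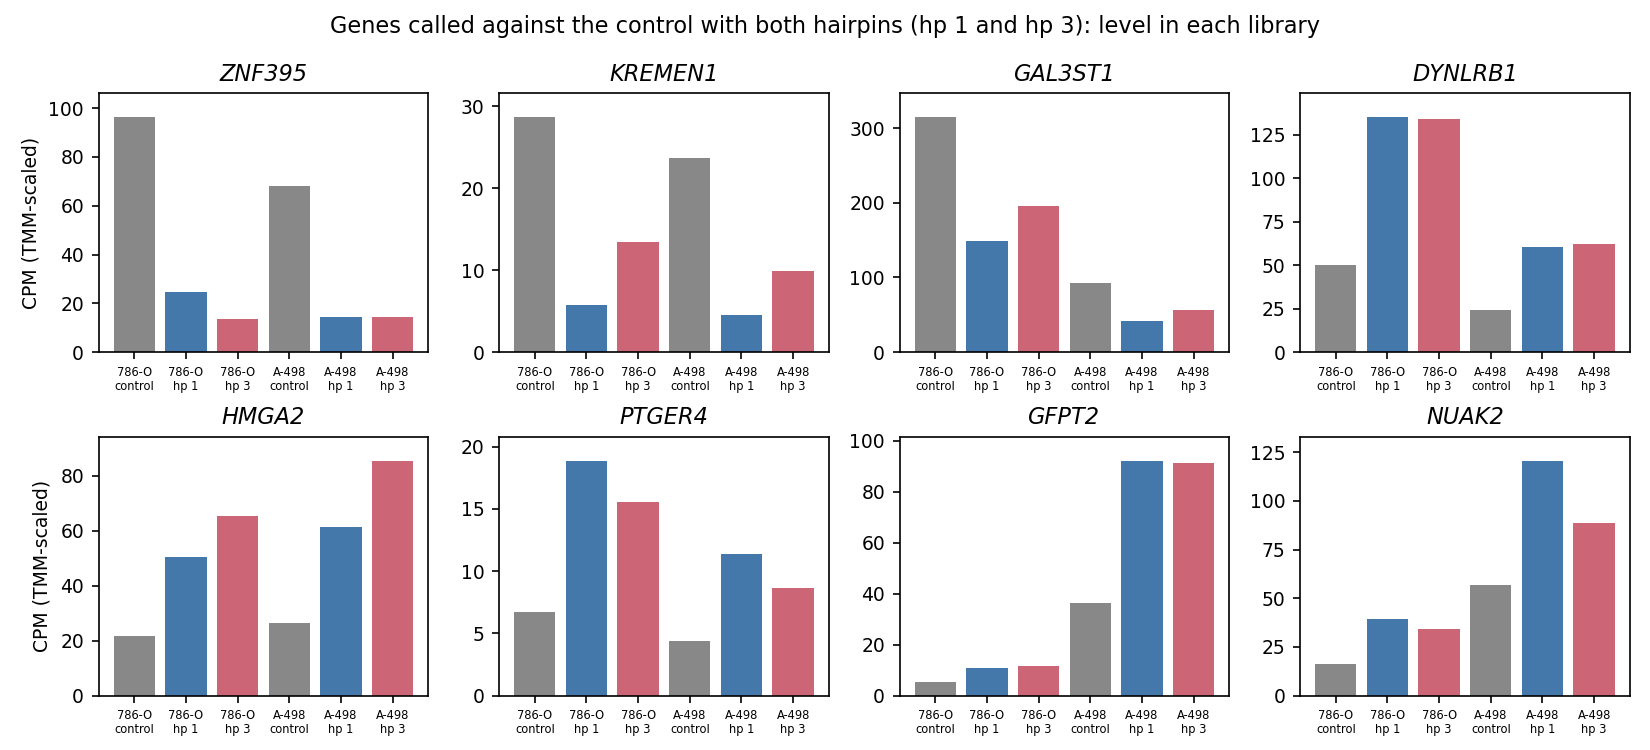
TMM-scaled CPM (y axes, from 0) of the 8 genes called with both hairpins, 1 bar per library (grey control, blue hairpin 1, red hairpin 3; hp stands for hairpin), with no error bars because each bar is a single library. ZNF395, KREMEN1 and GAL3ST1 were lower than the control in all 4 knockdown libraries, and DYNLRB1, HMGA2, PTGER4, GFPT2 and NUAK2 were higher.

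Of 30 gene lists tested between knockdown and control with camera, 4 passed, all upward. Interferon-stimulated genes, the antiviral response, had a positive fold for 41 of 42 measured members (median log2 0.788, adjusted p = 3.29e-16, and adjusted p = 0.88 with an estimated correlation), among them XAF1 (1.26) and the RNA sensor IFIH1 (1.05). NF-kB inflammatory genes had 30 of 33 positive (median 0.744, adjusted p = 9.48e-14, and adjusted p = 0.88 with an estimated correlation), led by the chemokine CXCL3 (1.71), the cytokine IL6 (1.5) and the NF-kB subunits NFKB2 (0.63) and RELB (0.66). Targets of ATF4, the transcription factor of the amino acid stress response, had 31 of 32 positive (median 0.698, adjusted p = 3.84e-07, and adjusted p = 0.88 with an estimated correlation), with the amino acid transporter SLC7A1 at 0.88. Targets of the growth regulators YAP and TEAD had 17 of 24 positive (median 0.208, adjusted p = 0.00189, and adjusted p = 0.88 with an estimated correlation), with ANKRD1 at 1.41, the ecto-nucleotidase NT5E at 1.60 and the receptor kinase AXL at 0.83. No member of any list was called over all genes. Adjusted over the list alone, 15 NF-kB and 4 YAP/TEAD members rose, and 0 interferon and ATF4 members did. ATF4 targets did not pass with hairpin 1 (median 0.182, adjusted p = 0.294), with which 8 of 32 were positive in 786-O (median -0.154) and 26 of 32 in A-498 (median 0.465), nor did YAP/TEAD targets (median 0.123, adjusted p = 0.272). The interferon medians with hairpin 1 and hairpin 3 were 0.292 and 0.021 in 786-O, against 1.824 and 1.149 in A-498. With an estimated correlation none of the 4 calls held, and fry called 0 lists in either of its tests. For knockdown against control the estimated correlations were 0.756 for interferon-stimulated genes, 0.305 for NF-kB genes, 0.76 for ATF4 targets and 0.189 for YAP/TEAD targets. All lie above the preset 0.01, so correlation between members may account for the loss. The settings also differ in more than the correlation. With hairpin 3 the YAP/TEAD list had an estimated correlation of -0.0269, yet its adjusted p in camera went from 6.40e-04 to 0.671. The estimated setting rests on the few residual degrees of freedom, so hardly any list can pass. A failure there does not show an absent shift. The interferon call was lost without the A-498 control (adjusted p = 0.104) and the YAP/TEAD call without the A-498 hairpin 3 library (adjusted p = 0.0783). With the hairpin block cholesterol synthesis (adjusted p = 0.0276) and renal tubule identity (adjusted p = 0.0400) joined these 4, both downward. The block was run with the preset correlation only, and it averages the hairpins. Cholesterol synthesis went opposite ways, with a median of 0.297 with hairpin 1 (camera adjusted p = 0.00654) and -0.793 with hairpin 3 (4.37e-06). The renal tubule medians were -0.166 (0.513) and -0.444 (0.0159).

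The other 26 lists did not pass between knockdown and control. Median log2 fold changes on the positive side were 0.078 for HIF targets (adjusted p = 0.901), 0.010 for glycolysis (0.482), 0.078 for proliferation (0.497), 0.216 for p53 targets (0.317), 0.190 for PPARG and adipogenesis (0.456), 0.082 for EMT and matrix (0.641), 0.217 for immediate early genes (0.101), 0.133 for apoptosis (0.240), 0.027 for ccRCC-associated genes (0.890), 0.046 for ribosomal proteins (0.317) and 0.045 for replication-dependent histones (0.317). On the negative side they were -0.036 for nuclear OXPHOS (0.453), -0.024 for mtDNA-encoded genes (0.476), -0.092 for the TCA cycle and beta-oxidation (0.240), -0.175 for cholesterol synthesis (0.286), -0.160 for fatty acid and lipid droplet genes (0.317), -0.104 for the UPR (0.317), -0.088 for NRF2 targets (0.240) and -0.268 for renal tubule identity (0.0680). The median and the test differed in sign for mitochondrial biogenesis and ribosome (median -0.004, test up, 0.901), TGF-beta targets (0.024, down, 0.901) and lysosome and autophagy (0.010, down, 0.901). Among markers of other cell types, endothelial markers had a median of 0.319 (0.101), immune markers 0.239 (0.456), fibroblast markers -0.188 (0.317) and HEK293-associated markers, those of the cells that packaged the virus, -0.218 (0.258).

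The authors' deposited table compares control with knockdown over the same 6 libraries and has 85 genes at an adjusted p under 0.05, 39 higher in the control and 46 lower. In the authors' deposited table ZNF395 has a log2 fold change of 1.82 (SE 0.234, adjusted p = 5.48e-11), positive because it sets control over knockdown. It is smaller in size than the 2.29 of edgeR and DESeq2 here, and whether the authors' fold changes were shrunken is not given in the sources used here. In edgeR 8 of the 85 genes were called with both hairpins, 65 with hairpin 3 only, 0 with hairpin 1 only, and 12 with neither. Over all genes edgeR called 1351 with hairpin 3 and 30 with hairpin 1, so a missing call with hairpin 1 does not show an absent change. Of the 85, 84 had the same sign in all 4 ratios to the control, against 29.6% of genes with a mean of at least 5 CPM. The 85 were chosen on a pooled fold over these same libraries, which favours a shared sign. The DESeq2 fit made here called 92 genes, and 84 of them are among the 85 of the authors' deposited table.

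Hairpin 1 against the control asked what the first construct alone changed, with the lines as replicates. ANXA5, a phosphatidylserine-binding annexin, fell (-2.56, SE 0.150, adjusted p = 0.0150), from 565 to 110 CPM in 786-O and from 938 to 139 in A-498. The clathrin adaptor gene AP1M1 (-1.94), the adaptor gene DOK4 (-1.31, adjusted p = 0.0215) and WRB (-1.59, adjusted p = 0.0215) also fell. CSF2, which encodes the cytokine GM-CSF, rose (3.06, SE 0.285, adjusted p = 0.0215), from 0.898 to 5.66 CPM in 786-O and from 0.491 to 5.55 in A-498, and the lysosomal protease gene CTSS rose by 1.41 (adjusted p = 0.0215). CSF2 and NUAK2 were the single members called over all genes in the NF-kB and YAP/TEAD lists. Both CSF2 and AP1M1 were picked after their values were seen. NF-kB genes passed upward (32 of 33 positive, median 0.911, adjusted p = 4.98e-20; 24 up adjusted over the list alone), as did interferon-stimulated genes (42 of 42, median 1.12, adjusted p = 1.05e-16; 23 up adjusted over the list alone) and cholesterol synthesis (21 of 24, median 0.297, adjusted p = 0.00654; 1 up adjusted over the list alone), and HIF targets passed downward (10 of 33 positive, median -0.179, adjusted p = 0.0445; 4 up and 9 down adjusted over the list alone). With an estimated correlation each of these lists had an adjusted p = 0.949. The cholesterol median was 0.630 in A-498 and -0.008 in 786-O, where 11 of 24 members were positive. In all, edgeR called 8 genes up and 22 down, and 23 of these 30 also differed between the hairpins. The count was 0 without the 786-O hairpin 1 library, 7 without the A-498 control, 608 and 488 without the hairpin 3 library of 786-O and A-498, 478 with no filter on low counts and 474 with DESeq2.

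Hairpin 3 against the control changed more genes, and several metabolic groups moved. Of 32 ATF4 targets, 20 rose (median 0.999, adjusted p = 2.81e-13, and adjusted p = 0.671 with an estimated correlation), among them STC2 (1.78, adjusted p = 0.0143), CEBPG (1.29, adjusted p = 0.0173) and SLC7A1 (0.97, adjusted p = 0.0224). ATF4 itself (1.26, adjusted p = 0.0145) and the amino acid synthesis genes ASNS (2.26, adjusted p = 0.0143) and PSAT1 (2.14, adjusted p = 0.0130), picked after their values were seen, rose too. ASNS went from 56.7 to 298 CPM in 786-O and from 83.0 to 352 in A-498. Of 24 cholesterol synthesis genes, 10 fell and 0 rose (median -0.793, adjusted p = 4.37e-06, and adjusted p = 0.671 with an estimated correlation), with LSS, picked after its values were seen, at -1.81 (adjusted p = 0.0121). Of 30 fatty acid and lipid droplet genes, 8 fell (median -0.324, adjusted p = 0.0418, and adjusted p = 0.671 with an estimated correlation), among them fatty acid synthase FASN (-0.86, adjusted p = 0.0278) and, picked after its values were seen, the desaturase SCD (-2.06, adjusted p = 0.0120).

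Other lists that passed with hairpin 3 were p53 targets, NF-kB and YAP/TEAD genes. Of 25 p53 targets 6 rose (median 0.497, adjusted p = 2.04e-04, and adjusted p = 0.671 with an estimated correlation), with GADD45A at 1.39 (adjusted p = 0.0121) and PLK3 at 0.80 (adjusted p = 0.0350), while CDKN1A, which encodes the cell cycle inhibitor p21, fell by 0.96 (adjusted p = 0.0307). Of 33 NF-kB genes 7 rose (median 0.459, adjusted p = 6.40e-04, and adjusted p = 0.671 with an estimated correlation), with CXCL3 at 1.93 (adjusted p = 0.0132) and IL6 at 1.23 (adjusted p = 0.0288). Of 24 YAP/TEAD targets 6 rose (median 0.396, adjusted p = 6.40e-04, and adjusted p = 0.671 with an estimated correlation), with NT5E at 1.88 (adjusted p = 0.0152) and AXL at 0.95 (adjusted p = 0.0220). Of 29 renal tubule genes 6 fell (median -0.444, adjusted p = 0.0159, and adjusted p = 0.671 with an estimated correlation), with the kidney transcription factor HNF4A at -1.65 (adjusted p = 0.0296) and the injury marker HAVCR1 at -0.67 (adjusted p = 0.0248), while PCK2 rose by 1.62 (adjusted p = 0.0190). HIF targets passed upward (median 0.341, adjusted p = 0.0336, and adjusted p = 0.671 with an estimated correlation) with members both ways, 4 up and 3 down, such as PFKFB3 (-0.93, adjusted p = 0.0143). The TCA cycle and beta-oxidation list (median -0.151, adjusted p = 0.0310, and adjusted p = 0.671 with an estimated correlation) had 4 members down, SUCLG2, ECHS1, ECI2 and IDH2 (-0.67, adjusted p = 0.0322). Interferon-stimulated genes (median 0.555, adjusted p = 3.66e-04, and adjusted p = 0.834 with an estimated correlation) and ribosomal proteins (median 0.160, adjusted p = 0.00205, and adjusted p = 0.834 with an estimated correlation) passed upward with no member called over all genes or adjusted over the list alone.

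Adjusted over the list alone, 29 ATF4, 15 p53, 14 NF-kB, 11 HIF and 6 YAP/TEAD members rose with hairpin 3, and 16 cholesterol, 10 renal tubule, 9 fatty acid and 6 TCA members fell. In the other direction 1 ATF4, 2 p53, 1 NF-kB and 3 HIF members fell, and 2 renal tubule members and 1 fatty acid member rose. By fry's mixed test, which counts change in either direction, ATF4 (adjusted p = 0.0277), p53 (0.00842) and NF-kB genes (0.00944) passed. So did lists that camera did not call, such as glycolysis (0.00262). Cholesterol synthesis (0.0539), interferon-stimulated genes (0.577) and ribosomal proteins (0.135) did not pass. The directional test of fry called no list, with renal tubule identity lowest (0.066). In all, edgeR called 514 genes up and 837 down, of which 185 and 470 changed by more than 2-fold. Of the 1351, 936 had the same sign with hairpin 1 and 893 differed between the hairpins. The shared controls favour a shared sign, and the number to be had with no effect was not simulated. The count was 121 without the A-498 control, 235 without the 786-O control, 882 without the 786-O hairpin 1 library, 2337 and 2076 without the hairpin 3 library of 786-O and A-498, 2654 with no filter and 2623 with DESeq2.

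**Figure D2:**
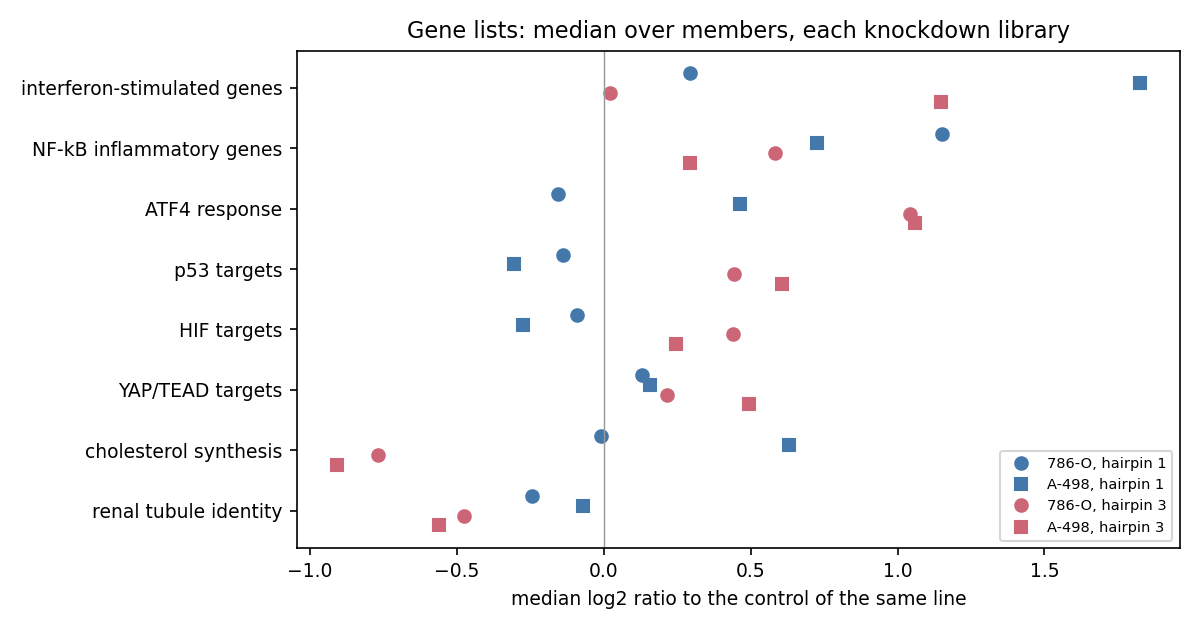
Median over list members of the log2 ratio to the control of the same line (x axis) for 8 gene lists (y axis), 1 point per knockdown library (blue hairpin 1, red hairpin 3; circles 786-O, squares A-498), with no error bars because each point is a single library. The ATF4 medians were 1.041 and 1.060 with hairpin 3, against -0.154 and 0.465 with hairpin 1, and the interferon medians were 1.824 and 1.149 in A-498, against 0.292 and 0.021 in 786-O.

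Hairpin 3 set directly against hairpin 1 asked which genes depended on the construct. ANXA5 (2.56, SE 0.150, adjusted p = 0.00390) and AP1M1 (2.29, SE 0.144, adjusted p = 0.00390) were higher with hairpin 3, together with the protease gene PAPPA2 (3.05, adjusted p = 0.00937), the glycine transporter gene SLC6A9 (2.56, adjusted p = 0.0256) and the homeobox gene BARX2 (2.26, adjusted p = 0.00821). SUCLG2, a subunit of succinyl-CoA ligase, was lower (-2.41, SE 0.192, adjusted p = 0.00659), at 24.7 CPM with hairpin 3 against 106 with hairpin 1 and 107 in the control in 786-O, and at 11 against 74.0 and 74.5 in A-498. The integrin gene ITGAX (-2.52, adjusted p = 0.00760), AIF1L (-2.43, adjusted p = 0.00971), PLEK (-2.30, adjusted p = 0.00914) and the focal adhesion gene TNS1 (-2.29, adjusted p = 0.00870) were lower too. By list, 19 of 32 ATF4 targets (adjusted p = 3.90e-11), 12 of 25 p53 targets (adjusted p = 1.04e-06) and 14 of 33 HIF targets (adjusted p = 3.04e-04, while 2 were lower) were higher with hairpin 3. With an estimated correlation each of these 3 lists had an adjusted p = 0.622. Lower were 15 of 24 cholesterol genes (adjusted p = 1.76e-08, and adjusted p = 0.622 with an estimated correlation) and 9 of 33 NF-kB genes (adjusted p = 0.00159, and adjusted p = 0.727 with an estimated correlation), while CXCL2 was higher. The ribosomal protein (adjusted p = 4.73e-05), YAP/TEAD (0.0194) and ccRCC-associated (0.0208) lists passed upward, the interferon (0.00693) and renal tubule (0.0351) lists downward. With an estimated correlation these 5 lists had an adjusted p between 0.622 and 0.949. Adjusted over the list alone, 26 ATF4, 15 p53 and 18 HIF members were higher with hairpin 3 and 0, 1 and 3 lower, while 18 cholesterol and 13 NF-kB members were lower and 1 of each higher.

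In all, edgeR called 823 genes higher and 1087 lower with hairpin 3. The count was 249 and 735 without the hairpin 1 library of 786-O and A-498, 1215 without the 786-O control, 3312 without the 786-O hairpin 3 library, 3117 with no filter and 2990 with DESeq2.

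The ratios to the control of the same hairpin in different lines correlated over 11026 genes with a mean of at least 5 CPM, ZNF395 left out, although genes are not independent replicates. The Pearson r was 0.507 for hairpin 1 in 786-O against hairpin 1 in A-498, and 0.620 for hairpin 3 against hairpin 3 (Spearman 0.499 and 0.642). Between different hairpins in different lines, which share no control, r was 0.095 for hairpin 1 in 786-O against hairpin 3 in A-498, and 0.223 for the reverse (Spearman 0.072 and 0.217). Over both lines the fold changes of the 2 hairpins, which share their controls, correlated with r = 0.269, against a mean of 0.498 in 20 simulations with no effect. The simulated r comes from the shared controls alone. Changes particular to 1 hairpin lower r, so the lower observed r does not show that the hairpins oppose each other. The covariance of these fold changes was 0.0385, against 0.0220 simulated, a difference of 0.0165. Between different hairpins in different lines, which share no control, the covariance was 0.0154 for hairpin 1 in 786-O against hairpin 3 in A-498, and 0.0493 for the reverse.

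**Figure D3:**
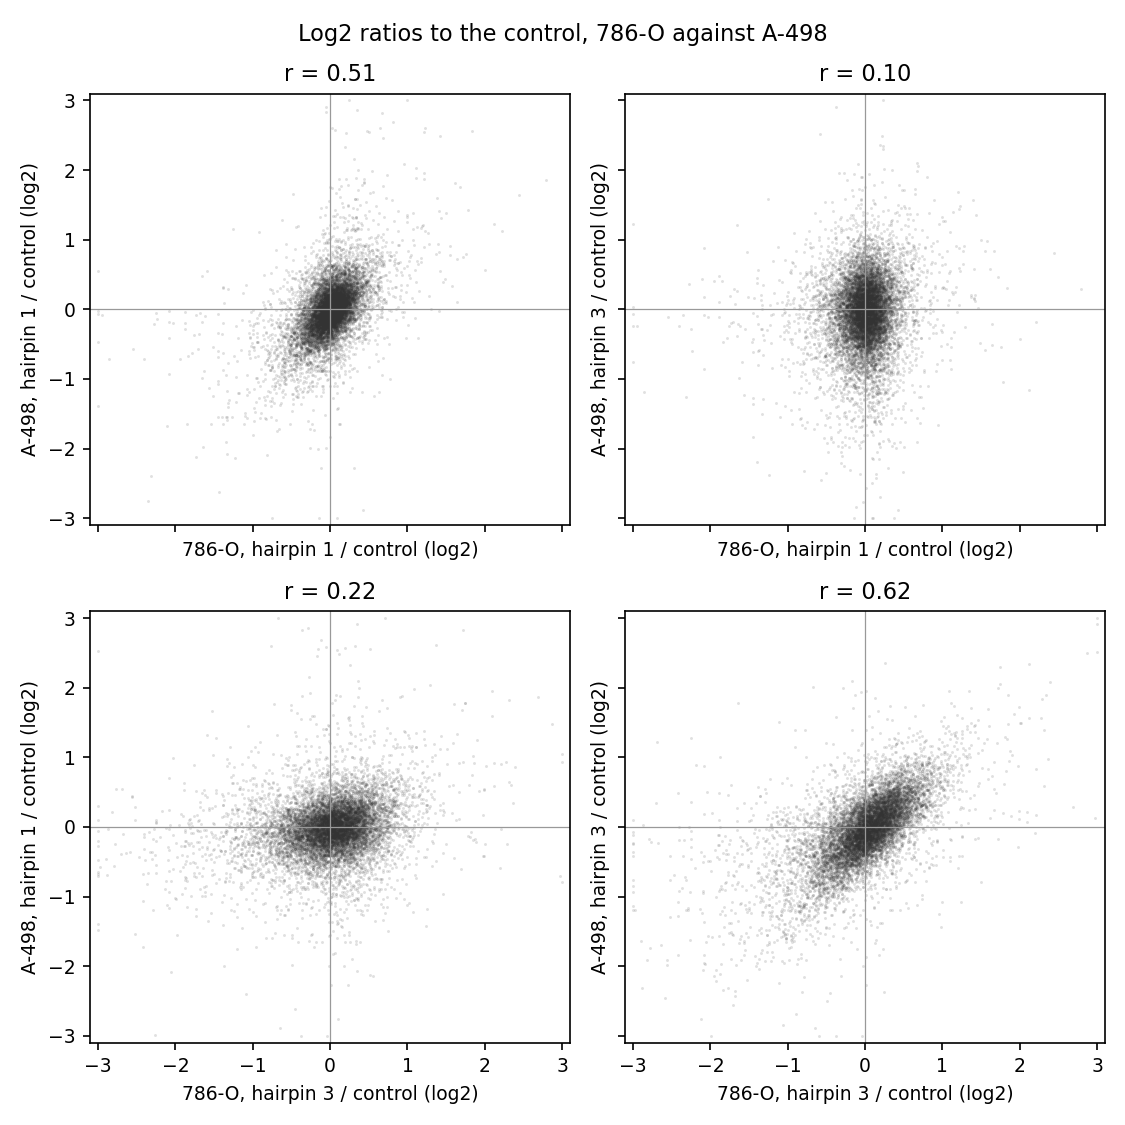
Log2 ratio to the control in 786-O (x axes) against A-498 (y axes) for each pairing of hairpins, 1 point per gene with a mean of at least 5 CPM, values limited to the axis range. The cloud runs along the diagonal where both axes show the same hairpin (r = 0.507 and 0.620) and is nearly round where they show different hairpins (r = 0.095 and 0.223).

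Within a line, the knockdown was tested with both hairpins as replicates against the lone control, which is assumed to vary like the knockdown libraries. With the hairpin as a block, a fit with 1 residual degree of freedom and 1 control library per line, 11 genes were called in A-498, and 9 of them were interferon-stimulated genes that rose: MX1 (2.43, SE 0.232), OAS1 (2.30), OAS2 (1.99), IFI44L (2.28), IFI6 (2.27) and IRF7 (2.35, each adjusted p = 0.0271), RSAD2 (2.14) and CMPK2 (2.56, each adjusted p = 0.0303) and IFIT1 (2.00, adjusted p = 0.0311). MX1, an antiviral GTPase, stood at 121 CPM in the A-498 control, 879 with hairpin 1 and 485 with hairpin 3, and at 2.62, 3.35 and 2.15 CPM in 786-O. ZNF395 was also among the 11 and fell (-2.22, adjusted p = 0.0303). In 786-O the block called 1 gene, AKR1C2, at 62 counts in the control and 2 with each hairpin. Apart from ZNF395, these genes were picked after their values were seen.

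Without the block edgeR called 0 genes in 786-O (334 at an unadjusted p under 0.05) and 0 in A-498 (348), whereas DESeq2 called 6 up and 8 down in 786-O (306) and 16 up and 8 down in A-498 (339). The difference between the lines in the response to knockdown was tested as an interaction, and edgeR (159 at an unadjusted p under 0.05) and DESeq2 (116) each called 0 genes, as did edgeR with the block. The smallest p-values, none passing (adjusted p = 1), belonged on the A-498 side to FBLN1, AKR1C2 and the interferon regulator IRF7 (2.12, SE 0.379), at 12.9, 65.1 and 66.1 CPM in the control, hairpin 1 and hairpin 3 libraries of A-498 and at 3.66, 4.19 and 4.37 in 786-O. On the other side were the glutathione transferase gene GSTP1, MAGI2-AS3 and SLC17A9, which were near 0 in all A-498 libraries (at most 0.171, 0.171 and 0.0903 CPM).

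The lines themselves differed far more than any construct, which gives the background for the comparisons within them. Higher in A-498 were the transcription factor gene SOX11, at 29.1 CPM in each A-498 library and at most 0.0127 in 786-O, PPP2R2C (62.1, 60.8 and 114 CPM in control, hairpin 1 and hairpin 3), the ephrin receptor gene EPHA7 (68.9, 36.1 and 78.2) and the protocadherin gene PCDHA10 (13.7, 6.37 and 13.8), which had no count in 786-O and shares exons with its cluster, so its counts are uncertain. Higher in 786-O were SHROOM4 (20.8, 17.3 and 10.8 CPM), ZNF702P (16.9, 15.9 and 12.5), the semaphorin gene SEMA6D (14.6, 11.8 and 11.4) and ZFP28 (9.55, 9.59 and 12.6), all without a count in A-498, and the F-box gene FBXL7 (30.7, 30.8 and 36.6), at most 0.01 CPM in A-498. Each of these 9 genes had an adjusted p of at most 4.99e-04 in edgeR. In all, 5182 genes were higher in A-498 and 4319 in 786-O, of which 4145 and 2452 differed by more than 2-fold. The count fell from 9501 to 5581 without the 786-O control and to 5607 without the A-498 control, and was 12460 with the hairpin as a block.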

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

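The tests of residual ZNF395, of a library standing apart and of the splits by knockdown, and the thinning, were chosen after the result was seen, and the test over genes without motif cores was chosen after the correlation over all genes and the leading motifs had been seen.

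Lists whose response to knockdown differed between the lines by camera with a preset correlation were taken for a closer look. Interferon-stimulated genes responded more in A-498 than in 786-O, by a median of 1.246 on the log2 scale over 42 genes, all of them positive (adjusted p = 1.78e-35, and adjusted p = 0.924 with an estimated correlation). Immediate early genes also responded more in A-498 (median 0.330, 18 of 24 positive, adjusted p = 0.00106, and adjusted p = 0.924 with an estimated correlation). For fibroblast markers the difference of A-498 minus 786-O was also positive (0.472, 7 of 10 positive, adjusted p = 0.0419, and adjusted p = 0.924 with an estimated correlation), with medians for hairpin 1 and hairpin 3 of -0.051 and -0.097 in A-498, against 0.070 and -0.484 in 786-O. NF-kB inflammatory genes responded less in A-498 (-0.315, 9 of 33 positive, adjusted p = 0.0119, and adjusted p = 0.950 with an estimated correlation). For replication-dependent histones the difference was negative (-0.459, 7 of 23 positive, adjusted p = 0.00718, and adjusted p = 0.924 with an estimated correlation), with medians of -0.376 and 0.032 in A-498, against 0.329 and 0.222 in 786-O. No single gene passed the interaction test in edgeR (159 at an unadjusted p under 0.05) or in DESeq2 (116).

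The pattern most in need of a second look is that 1910 genes differed between the 2 hairpins in edgeR. Residual ZNF395 as the cause predicts little difference in A-498, where hairpin 3 left 0.981 of the hairpin 1 level, yet the SD over genes of the hairpin difference there was 1.098 times that in 786-O, where the ratio was 0.546. Library size is argued against by 1923 genes after thinning to the smallest library, GC content and transcript length by the share of 0.0056 of the variance that they explain, and a single odd library by the correlation of 0.577 between the lines. Matches to each hairpin's leading motif in 3' untranslated regions as the whole cause are argued against by a correlation between lines of 0.506. That correlation was taken over 4292 genes with no core of these motifs there. Other motifs were not excluded. Among those that went with falls with hairpin 3, CTTCTGC ranked 8 in 786-O and 4 in A-498. Matches in coding sequences were not searched. Direct matches of those kinds, and secondary effects of any match, therefore stay open. A candidate explanation that remains is that each hairpin acts on transcripts other than ZNF395, directly or through them, as the motif tests with a rank of 1 for each hairpin leave open, and no explanation through the biology of ZNF395 was tested beyond its residual level.

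The split of the 6 libraries by line called 9501 genes and the highest of the other 9 splits into 3 and 3 called 0, so that 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For knockdown, 9 splits take 1 library of each line as the reference. The real split called 0 genes, so that all 9 necessarily called as many, and 9 splits are also too few for a share under 0.05. The highest other, with hairpin 3 as the reference in both lines, called 1450 genes, while hairpin 1 as the reference in both lines called 1. The count of 1450 points to a structure of the samples in which the hairpin 3 libraries stand apart from the rest.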

How the results depend on the processing

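The counts of genes called with both hairpins, the thinning and the lists under the hairpin comparisons were chosen after the data were seen. Over 12 results and 129 alternatives, 82 values kept their side of the threshold or stayed within 1.5 times the main count, 45 moved by more, 2 became significant and none reversed. Thinned to the smallest library, hairpin 3 against hairpin 1 gave 1923 genes, against 1910 at full depth, and depth was not varied for the other results. DESeq2 called 51 genes up and 41 down for knockdown (edgeR 0 and 0), 14 within 786-O and 24 within A-498 (edgeR 0 and 0), 474 with hairpin 1, 2623 with hairpin 3, 2990 between hairpins and 151 with both hairpins, and gave ZNF395 a log2 fold change of -2.29 with an adjusted p = 6.49e-11, where the other alternatives without the block ranged from 0.104 to 1. With no filter on low counts edgeR called 478 genes with hairpin 1, 2654 with hairpin 3, 3117 between hairpins and 162 with both. limma-voom called 1 gene down for knockdown. The hairpin as a replicate block called 9 genes up and 17 down for knockdown, 1 within 786-O and 11 within A-498, and gave ZNF395 a log2 fold change of -2.30 (adjusted p = 0.0176). It also brought the genes called between the lines from 9501 to 12460 and the called lists from 4 to 6, and changed no other call. Of the 30 lists, 4 were called, 0 with an estimated correlation and 0 with either test of fry, against 11 with hairpin 3 and 10 between hairpins. For each of these moves the cause was not tested.

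Leaving out each library in turn gave 0 to 0 genes up and 0 to 0 down for knockdown, 0 to 0 within each line and for the difference between lines, and a ZNF395 log2 fold change from -2.50 to -2.12. Counts ran from 5581 to 8587 between the lines, lowest without the 786-O control, and from 0 to 608 with hairpin 1, lowest without the 786-O hairpin 1 library and highest without the 786-O hairpin 3 library. They ran from 121 to 2337 with hairpin 3, lowest without the A-498 control and highest without the 786-O hairpin 3 library, and from 249 to 3312 between hairpins, lowest without the 786-O hairpin 1 library and highest without the 786-O hairpin 3 library. Genes called with both hairpins ran from 0 to 165, lowest without the 786-O hairpin 1 library and highest without the A-498 hairpin 3 library. Called lists ran from 3 to 9, lowest without the A-498 hairpin 3 library and highest without the A-498 hairpin 1 library. The difference between lines and the knockdown within a line need that line's control and were not run without it. A line left with 1 library of a group is assumed to vary like the others. In the model with line and construct, a fit without a library has 1 residual degree of freedom. The construct concerned is then left with 1 library, so the numbers of genes called with each hairpin are unstable. The cause of these moves was not tested. A change of pseudocount was not run, since the table holds counts.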

Other observations

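The tests of motif rank in this part were planned before their results were seen. The genes named for the presence of a motif were chosen afterwards. The shares of called genes with a motif were not among the planned predictions.

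The genes of the interferons themselves were counted in A-498, and those named here were picked after their values were seen. IFNB1, the gene of interferon beta, had 10 counts in the A-498 control, 71 with hairpin 1 and 73 with hairpin 3, and 1, 2 and 2 counts in 786-O. With hairpin 3 it rose in the test over both lines (log2 fold change 2.71, adjusted p = 0.0307), and with hairpin 1 it had a log2 fold change of 2.93 that did not pass (adjusted p = 0.132). IFNL1, of the lambda interferons, had 9, 26 and 69 counts in A-498 and 0 in each 786-O library. IFNL2 and IFNL3, near-identical copies whose counts are uncertain, had 5, 7 and 7 and 1, 10 and 14 counts in A-498. CCL2, a monocyte attractant also picked afterwards, stood at 59.7, 160 and 29.1 CPM in the control, hairpin 1 and hairpin 3 libraries of A-498 and at 2.91, 10.1 and 4.88 in 786-O, and was lower with hairpin 3 than with hairpin 1 (-1.72, adjusted p = 0.0419).

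Of genes of the hypoxia response, 4 that differed between the hairpins were picked after their values were seen. EPAS1, which encodes HIF-2alpha, the transcription factor that accumulates in cells without VHL, was higher with hairpin 3 than with hairpin 1 (1.24, SE 0.132, adjusted p = 0.00899), at 259 against 122 CPM in 786-O with 158 in the control, and at 208 against 78.4 in A-498 with 115 in the control. NDRG1 stood at 820, 389 and 974 CPM in the control, hairpin 1 and hairpin 3 libraries of 786-O and at 667, 227 and 872 in A-498 (difference 1.63, adjusted p = 0.00899). The collagen cross-linking gene LOX (1.92, adjusted p = 0.00821) and the glucose transporter gene SLC2A3 (2.08, adjusted p = 0.00609) were higher with hairpin 3 as well.

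RNU6-1, a U6 small nuclear RNA gene picked after its values were seen, has near-identical copies and is therefore uncertain. It had 44 counts in the 786-O control and 60 in the A-498 control and 0 in all 4 knockdown libraries. Its relative RNU6-26P had 129, 117 and 151 counts in 786-O and 169, 102 and 170 in A-498.

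The hypothesis that each hairpin lowers transcripts that match its guide from the seed was tested with motifs in 3' untranslated regions. Among all 7-mers, with those in fewer than 50 genes set to no shift, ACACGTC went with the strongest falls with hairpin 1 in 786-O and ranked 1 in A-498 as well (250 genes, mean shift -0.285 and -0.323 on the log2 scale), against ranks 2338 and 5309 with hairpin 3. For hairpin 3 the leading 7-mer in 786-O was TTACTGA, which again ranked 1 in A-498 (1632 genes, -0.138 and -0.159), against ranks 10927 and 11667 with hairpin 1. With a rank of 1 in the second line each, a seed-type off-target of hairpin 1 and a seed-type off-target of hairpin 3 may account for part of the falls. Of searched genes called down with hairpin 1, 9 of 21 (42.9%) held ACACGTC, against 2.4% of genes not called. With hairpin 3, 172 of 590 (29.2%) held TTACTGA, against 15.5%. Most called falls of either hairpin thus lacked its exact 7-mer. The motifs were chosen from falls in these same libraries, so these shares are no separate test. The guide sequences are not given in the sources used here, so the match of motif to guide is untested.

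Each motif occurs once in the ZNF395 transcript, in which 22.4% of all 7-mers occur at least once. With its flanks from other leading 7-mers, the first reads GACACGTCAA and lies on chromosome 8 at 28352588 to 28352597 (GRCh38), in the coding sequence in exon 6 of 10. The second reads TTACTGATTA and lies at 28347779 to 28347788, in the 3' untranslated region in exon 10 of 10. ANXA5 holds the motif of hairpin 1 in its 3' untranslated region, DPM1 holds that of hairpin 3, and KREMEN1, GAL3ST1 and CLDN2 hold neither exact 7-mer there. Other leading 7-mers and the coding sequences of these genes were not looked up, so other matches stay open for them. ACTG1 holds the motif of hairpin 1 and not that of hairpin 3 in its 3' untranslated region. In edgeR it was called with hairpin 3 (log2 fold change -1.13, adjusted p = 0.0292) and not with hairpin 1 (-1.33, adjusted p = 0.105). The exact 7-mer TTACTGA in that region therefore does not account for its fall with hairpin 3. Other leading 7-mers of hairpin 3, such as TACTGAA and TACTGAT, and its coding sequence were not searched, so other matches stay open.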
